A study of Caenorhabditis elegans with 18 samples.

How the data were processed

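DNA from chromatin immunoprecipitation (IP) of formaldehyde-fixed Caenorhabditis elegans N2 embryos was hybridised to tiling arrays. There were 9 IPs: 3 with an antibody to DPY-27, 3 with an antibody to SDC-3 and 3 with no antibody. Per the labels, the 3 IPs of a group were independent biological experiments. Each IP was hybridised, together with its input DNA as the reference, to 2 array designs, which gives 18 arrays. Array 1 carried probes of chromosomes I, II and III and of IV up to position 6157299. Array 2 carried the rest of IV, V, the X and 157 mitochondrial probes. Each design held 577211 genomic probes, and the starts of neighbouring probes lay a median of 86 bp apart. IP 2 of every group was labelled with Cy3 and its input with Cy5, and the other IPs had the opposite labelling, so dye orientation was balanced over the groups.

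The deposited value of each probe was the log2 ratio of IP to input, from which the authors had subtracted 1 constant per array. This unit was checked on the 6 no antibody arrays, the only ones with scanner data used here. On these the deposited log2 values and the ratios computed from the scanner files correlated with r of at least 0.9999, and 100% of the probes differed by no more than 0.006 once the constant was removed. For the other 12 arrays the direction of the ratio rests on the dyes given in the labels. The scanner files held the raw spot intensity of each dye, extracted per the file headers with NimbleScan 2.3.16 or 2.3.17 and without background subtraction. The deposited autosomal median was 0 on every array. The genome build of the array positions was not given in the sources used here. Positions are therefore those of the arrays, no gene was assigned to a position, and the planned comparisons of gene starts and of gene lists, including the lists fixed beforehand, were not run.

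Depth does not apply to arrays, and the number of IPs limits the precision. On the 6 arrays with scanner files the median input intensity of genomic probes was 9.51 to 27.2 times that of 80000 random-sequence probes, and 93.4% to 97.6% of genomic probes lay above the 95th percentile of the random probes in the input channel.

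Each array was centred on the median of all its probes, and probe values were averaged in 1000 bp windows with at least 4 probes. This gave 50295 windows on array 1 and 49992 on array 2, with a median of 12 probes. Centring moved array 2 down by 0.19 to 0.20 for DPY-27 and by 0.06 to 0.14 for SDC-3 relative to its autosomes, since the X made up part of that array. Autosomal values of these groups are therefore low by that amount, and window counts with each array centred on its autosomal median are given beside the main ones. For each array design, limma 3.58.1 (lmFit and eBayes) in R 4.3.3 was fitted to all 9 IPs with 1 mean per group and no covariate. The contrasts were DPY-27 minus no antibody, SDC-3 minus no antibody and SDC-3 minus DPY-27. P-values were adjusted by Benjamini-Hochberg over all windows of a design, and windows with an adjusted p under 0.05 were called. Whether the replicate number pairs IPs of different groups was checked by the correlation across windows of their deviations from the group means. For SDC-3 and DPY-27 all 3 pairs of the same number were over 0.1, at 0.15 to 0.46 on array 1 and 0.46 to 0.77 on array 2, so the numbers were taken to pair these IPs. This rests on the data and not on the labels, and it was settled for this comparison alone after the calls had been seen, so the fit without a block stayed the main one and counts with the replicate number as a block are given where they move. Sites were runs of enriched windows with at most 1 uncalled window between them, and a site was shared if it overlapped a site of the other protein by at least 1 base. Chromosome values were computed per IP as the mean over probes and compared between groups of 3 by a two-sided exact permutation test, for which the smallest possible p is 0.1. Other tools were data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

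The contrasts, tests, window size, thresholds, the rule for named sites and the alternatives listed in this paragraph were chosen before the data were examined. The rule named, for each protein, the 12 X sites and the 8 autosomal sites with the largest log2 difference from no antibody in their peak window, among sites whose peak window had all 3 IPs above all 3 no antibody IPs. It also named the 5 called windows with the largest difference between SDC-3 and DPY-27 in each direction. The alternatives chosen in this way were autosomal centring, no centring, scaling of every array to 1 median absolute deviation, windows of 500 and 2000 bp, medians over probes, no minimum of probes, an adjusted p under 0.01, a log2 difference of at least 1, the dye or the replicate number as covariates, fits of 2 groups, input as the only control, removal of the 10% of probes with the dimmest input, each IP left out in turn, other distances and overlaps for sites, and scanner intensities with and without loess correction (a span of 0.3 on 20000 probes) for the no antibody arrays.

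Several steps were chosen after seeing the data. DPY-27 sites covered nearly the whole X, so foci were defined against the local level. The running median of 51 windows was subtracted from each window of each IP, limma was fitted to the remainder, p-values were adjusted over X and autosomal windows apart, and called windows with a local log2 difference of at least 1 were joined over at most 1 window. The level far from foci (at least 20 kb), the ratio of the excess at foci to that far from foci, runs of windows lower in SDC-3 than in DPY-27, the placement of foci against 10000 random placements, the adjustment over X and autosomal windows apart, the use of Cy5-labelled IPs alone and the list of windows with high no antibody values were added in the same way.

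The window step was tested on simulated data with the measured spread. For DPY-27 minus no antibody, with 200 windows raised per size, it recovered 100% of those raised by 1 on the log2 scale on array 1 and 98.0% on array 2, and 50.5% and 23.0% of those raised by 0.5. It made 18 false calls among 319 on array 1 and 13 among 255 on array 2. The focus step, tested on array 2 for the same contrast over 49978 windows, recovered 100% of 200 windows with a local excess of 1.5 and of 2, with at most 1 false window. The chance correlation between the comparisons that share the no antibody controls came from 20 simulations of unchanged groups. The chance overlap of autosomal calls on array 2 came from 20 simulations, added after seeing the data, in which both proteins had the measured X and unchanged autosomes.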

Results

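The dosage compensation complex binds the X chromosomes of C. elegans hermaphrodites and lowers their expression. DPY-27 is its condensin-like SMC subunit, and SDC-3 is a zinc finger protein needed to bring the complex to the X. Binding of both proteins was measured in embryos by ChIP-chip, with 3 IPs per antibody and 3 IPs without antibody, each on 2 array designs. Values are log2 ratios of IP to input with each array centred on its median, given as the mean ± SD of 3 IPs unless a difference is named. Windows are 1 kb long and are named by chromosome and first base in array coordinates. The arrays gave 17719 windows on the X, 82554 on the autosomes and 14 on the mitochondrial genome.

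The first question was how far each protein favours the X over the autosomes. Both did so in each of their 3 IPs, and the control did not. The X exceeded the autosomes of the same array by 0.91 ± 0.21 for DPY-27 (SD, n = 3), a 1.88-fold higher ratio. For SDC-3 the excess was 0.39 ± 0.17, or 1.31-fold. Without antibody it was 0.00098 ± 0.0090. The IPs gave 1.10, 0.95 and 0.69 for DPY-27 and 0.50, 0.49 and 0.19 for SDC-3, the second value of each being the dye-swapped IP. The difference from no antibody was 0.91 for DPY-27 and 0.39 for SDC-3, and SDC-3 minus DPY-27 was -0.52. Each comparison had an exact permutation p of 0.1, the smallest that 3 against 3 IPs allow. With all arrays scaled to one median absolute deviation the difference between the proteins was -0.28. That scale was taken over all probes of an array, X included, so an enriched X enters it. Scaling took the X excess from 0.91 to 0.65 for DPY-27 and from 0.39 to 0.37 for SDC-3. The smaller difference may thus partly follow from the scaling, which was not tested.

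**Figure D1:**
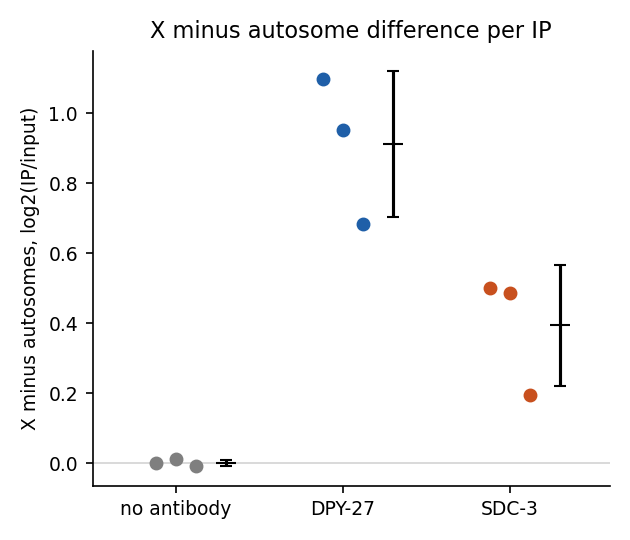
Mean log2(IP/input) of X probes minus that of autosomal probes on array 2, for each IP (points) with the mean and SD of the 3 IPs per group (bars). DPY-27 lies at 0.69 to 1.10, SDC-3 at 0.19 to 0.50 and no antibody near 0.

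DPY-27 against no antibody asked where on the genome the condensin subunit lies. It was spread over almost the whole X, with sharp peaks on a raised floor. The strongest was the window at X 5,429,001, with 3.91 ± 0.33 in DPY-27 and 0.30 ± 0.09 without antibody. Further peaks lay at X 6,296,001 (3.56 ± 0.48), X 11,937,001 (3.45 ± 0.41), X 16,056,001 (3.39 ± 0.34) and X 4,209,001 (3.47 ± 0.44). The other 7 of the 12 named X sites peaked at X 16,681,001, X 13,700,001, X 12,363,001, X 9,465,001, X 2,997,001, X 17,545,001 and X 13,514,001, and over all 12 the difference from no antibody was 3.09 to 3.62. On the X 16110 windows (90.9%) were enriched (17278 with autosomal centring) and 3 were lower than in the control, with a median difference of 0.67 (limma, adjusted p under 0.05). Those 3 windows, named after their values were seen, were X 73,001 (-0.30), X 5,908,001 (-1.23) and X 5,911,001 (-1.06), and in the last 2 the no antibody IPs themselves were high. The enriched windows formed 249 sites with a median length of 29000 bp and a maximum of 540000 bp.

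**Figure D2:**
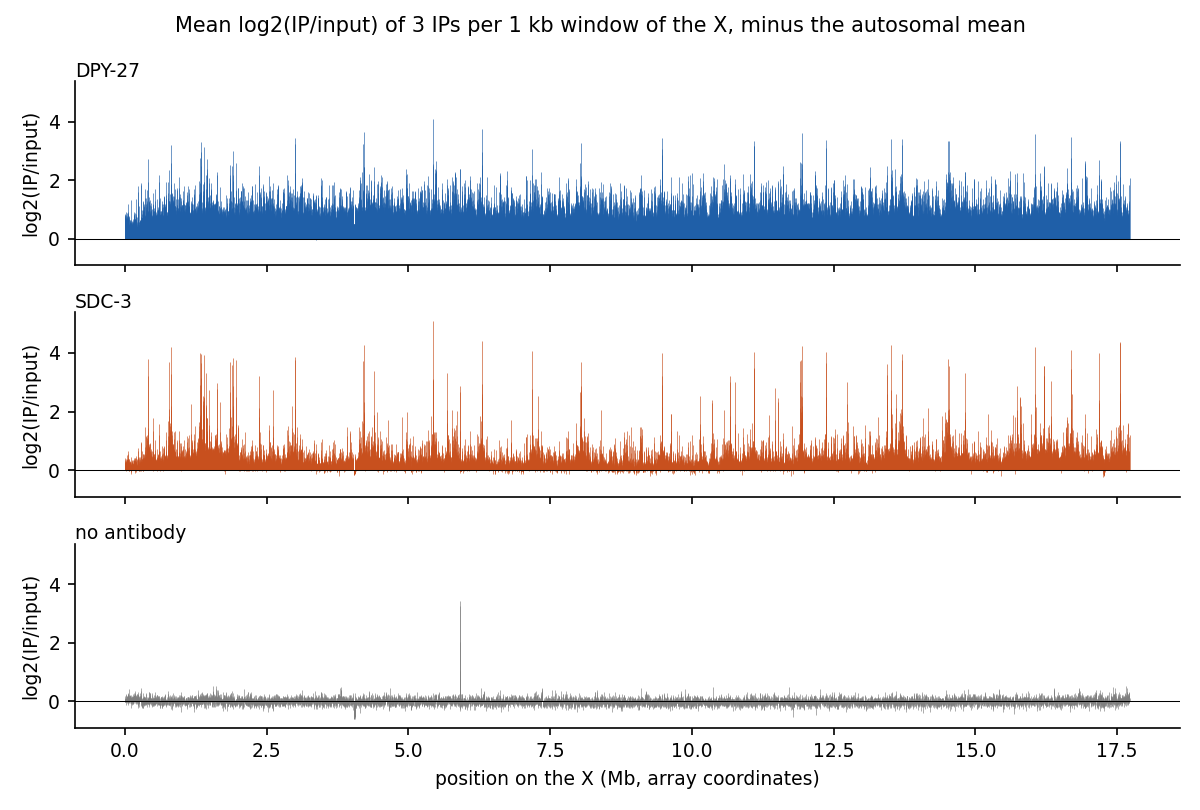
Mean log2(IP/input) of 3 IPs per 1 kb window along the X, minus the autosomal mean of the same IPs, for DPY-27, SDC-3 and no antibody. DPY-27 and SDC-3 peak at shared positions such as X 5,429,001, DPY-27 is raised between the peaks, and the single high no antibody peak spans X 5,908,001 to X 5,911,001.

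Autosomal DPY-27 signal was sparse and weak beside that of the X. The largest was at IV 3,367,001, where DPY-27 reached 1.08 ± 0.23, against -0.19 ± 0.03 without antibody and 0.04 ± 0.06 for SDC-3 (adjusted p of DPY-27 0.00155). II 13,599,001 (difference 1.11, adjusted p 0.0266) and IV 2,275,001 (1.09, adjusted p 0.00702) followed. The remaining named sites, IV 7,592,001, II 13,825,001, I 5,983,001, I 5,316,001 and IV 14,779,001, had differences of 0.87 to 0.99, and IV 7,592,001 and IV 14,779,001 lost their call when X and autosomal windows were adjusted apart. Both of these lie on array 2, where centring lowered DPY-27 by 0.19 to 0.20. Their differences are low by that amount beside those of array 1, so their place in this order depends on the centring. Most of these calls are fragile: of the 8 named sites, IV 3,367,001, IV 7,592,001 and IV 14,779,001 kept their call without no antibody IP 1, no antibody IP 2 or DPY-27 IP 2, and only the last 2 of these did with equal median absolute deviations. A kept call on array 2 does not mark a sturdier site, since adjustment together with the X admits autosomal windows more readily there. At IV 7,592,001 the DPY-27 IPs ran from 0.25 to 1.53. SDC-3 was 0.52 ± 0.05 at IV 2,275,001, 0.62 ± 0.13 at II 13,825,001 and 0.61 ± 0.11 at I 5,316,001. At II 13,599,001, IV 7,592,001, I 5,983,001 and IV 14,779,001 SDC-3 was -0.06 to -0.02. In all, DPY-27 was higher than the control in 130 autosomal windows and lower in 5047. With autosomal centring the counts were 722 and 141, so the direction of most autosomal calls depends on the centring, and with X and autosomal windows adjusted apart they were 12 and 0, all on array 1. On array 2 the main adjustment called 118 autosomal windows higher, and simulations with unchanged autosomes beside the measured X called a mean of 217. The simulated autosomes were not lowered by centring as the measured ones were, so these counts are not on the same scale. The 130 became 71, 64 and 56 without no antibody IP 1, 2 and 3, 65 and 53 without DPY-27 IP 1 and 2, and 253 without SDC-3 IP 2, and the 5047 became 2464, 2382 and 2864 without no antibody IP 1, 2 and 3 and 1881 and 2966 without DPY-27 IP 1 and 2.

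SDC-3 against no antibody asked the same of the recruiting protein. SDC-3 stood in peaks on the X, with lower values between them. The window at X 5,429,001 again had the highest value, 4.99 ± 0.29 for SDC-3. It was followed by X 6,296,001 (4.30 ± 0.44), X 17,545,001 (4.25 ± 0.34), X 13,514,001 (4.18 ± 0.28) and X 4,209,001 (4.16 ± 0.27). Besides X 16,056,001, X 11,937,001 and X 16,681,001, the SDC-3 list held 4 sites outside the DPY-27 list: X 7,181,001 (3.97 ± 0.40), X 806,001 (4.08 ± 0.28), X 1,323,001 (3.89 ± 0.39) and X 17,181,001 (3.90 ± 0.39). On the X 2108 windows (11.9%) were enriched and 0 depleted, with a median difference of 0.20, and they formed 953 sites with a median length of 1000 bp. The widths of the peaks of the proteins could not be told apart. The mean peak at foci of the other protein was 1.71 ± 0.08 kb wide at mid-height for SDC-3 and 1.60 ± 0.07 kb for DPY-27. Both mean profiles were already below mid-height in the windows next to the peak window, so 1 kb windows cannot resolve a difference. The foci also differed between the proteins. The 2108 fell to 943, 1073 and 913 without no antibody IP 1, 2 and 3 and to 872 without SDC-3 IP 1, and rose to 3734 without SDC-3 IP 3. The count was 3557 with autosomal centring and 3317 with X and autosomal windows adjusted apart.

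SDC-3 also had autosomal sites, several of them strong. The highest was V 9,701,001, with 2.49 ± 0.84 for SDC-3, 0.34 ± 0.19 for DPY-27 and -0.10 ± 0.04 without antibody (adjusted p of SDC-3 0.000333). II 12,551,001 reached 2.13 ± 0.68, V 3,044,001 1.96 ± 0.52, V 7,649,001 1.63 ± 0.52 and V 7,659,001 1.15 ± 0.39, while DPY-27 was at or below 0.24 in these 4 windows. I 14,121,001 (1.17 ± 0.18), IV 14,033,001 (0.96 ± 0.33) and II 4,701,001 (0.95 ± 0.18) completed the named sites, of which IV 14,033,001 lost its call when X and autosomal windows were adjusted apart. There DPY-27 was 0.33 ± 0.09, 0.43 ± 0.34 and 0.34 ± 0.08, in the same order. SDC-3 minus DPY-27 was called at I 14,121,001 but not at IV 14,033,001 (limma, adjusted p 0.14) or II 4,701,001 (0.22). In all, SDC-3 had 176 autosomal windows enriched and 93 depleted. The counts were 388 and 12 with autosomal centring and 219 and 747 with equal median absolute deviations. They were 108 and 0 with X and autosomal windows adjusted apart. The 176 fell to 29, 51 and 24 without no antibody IP 1, 2 and 3, to 90, 103 and 98 without DPY-27 IP 1, 2 and 3, and to 25 and 103 without SDC-3 IP 1 and 2. The 93 became 5, 12 and 7 without no antibody IP 1, 2 and 3, 54 and 30 without DPY-27 IP 1 and 2, and 2, 233 and 434 without SDC-3 IP 1, 2 and 3.

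SDC-3 against DPY-27 asked where the recruiting protein and the condensin subunit part. SDC-3 was the lower of the 2 over most of the X and the higher at its strongest peaks. At all 12 named DPY-27 X sites SDC-3 lay above DPY-27, by 0.59 at X 9,465,001 to 1.10 at X 17,545,001, and 9 of these differences were called (12 with the replicate number as a block). These are the extremes of the DPY-27 peaks: among foci, defined after seeing the data, SDC-3 was higher at 36 of the 50 strongest of DPY-27 and at 49 of all 200, with a median difference of -0.78. At the foci of SDC-3 it was higher at 100 of 158, with a median difference of 0.33. Each list of foci favours the protein by which it was picked. SDC-3 exceeded DPY-27 by 1.40 at X 17,181,001 and by 1.30 at X 1,323,001. In the other direction, the windows at X 16,933,001, X 16,934,001, X 16,935,001, X 16,937,001 and X 16,941,001 had 2.05 to 2.25 for DPY-27 and 0.35 to 0.53 for SDC-3. Of the X windows 10116 (57.1%) were lower in SDC-3 and 105 higher (12647 and 87 with autosomal centring, 181 higher with the block), with a median difference of -0.46. The 10116 fell to 3407 and 5816 without DPY-27 IP 1 and 2 and to 6510 without SDC-3 IP 3. They fell to 1906 with equal median absolute deviations, a scale into which the X signal itself enters. The 105 became 68 without DPY-27 IP 2, 63 without SDC-3 IP 1 and 224 without SDC-3 IP 3, and the 9 became 3 without DPY-27 IP 2 or SDC-3 IP 1, 5 without DPY-27 IP 3, 6 with autosomal centring, 4 with 2 groups in the fit and 1 with Cy5-labelled IPs alone, although all 12 stayed higher in SDC-3 under every alternative fitted to 1 kb windows.

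**Figure D3:**
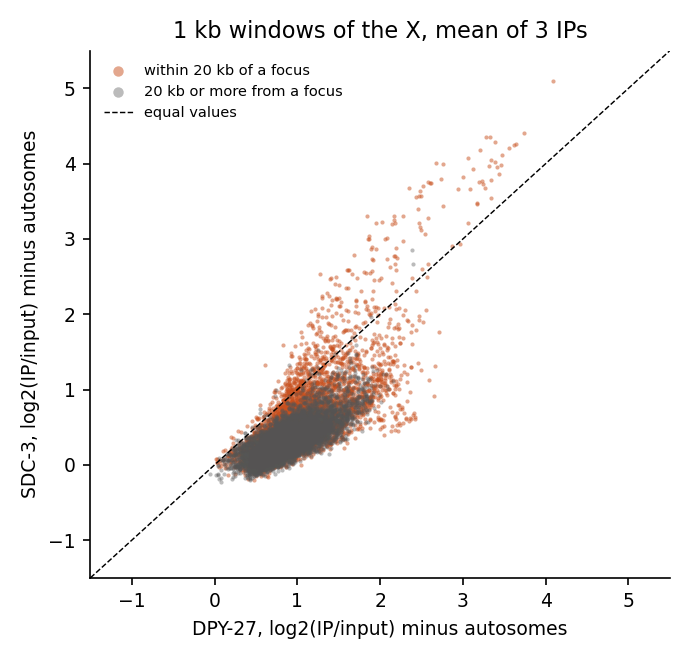
SDC-3 against DPY-27 for each 1 kb window of the X (mean log2(IP/input) of 3 IPs minus the autosomal mean), with windows within 20 kb of a focus in orange, others in grey and equal values as a dashed line. Most windows lie below the line, and the windows with the highest DPY-27 values lie above it.

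On the autosomes the largest differences between the proteins were all higher in SDC-3: V 9,701,001 (2.15), V 3,044,001 (1.96), II 12,551,001 (1.89), V 3,040,001 (1.88) and V 3,041,001 (1.76). In all, 144 autosomal windows were higher in SDC-3 and 25 lower, against 36 and 50 with autosomal centring and 487 and 50 with the replicate number as a block. With X and autosomal windows adjusted apart 4 remained higher, V 3,044,001, II 12,550,001, II 12,551,001 and I 14,121,001, and 1 lower, IV 3,367,001, the top autosomal DPY-27 site. The 144 fell to 61 and 77 without no antibody IP 1 and 2, to 24, 60 and 93 without DPY-27 IP 1, 2 and 3 and to 89 without SDC-3 IP 1. The 25 became 13, 14 and 14 without no antibody IP 1, 2 and 3, 5, 7 and 42 without DPY-27 IP 1, 2 and 3, and 15 without SDC-3 IP 1.

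**Figure D4:**
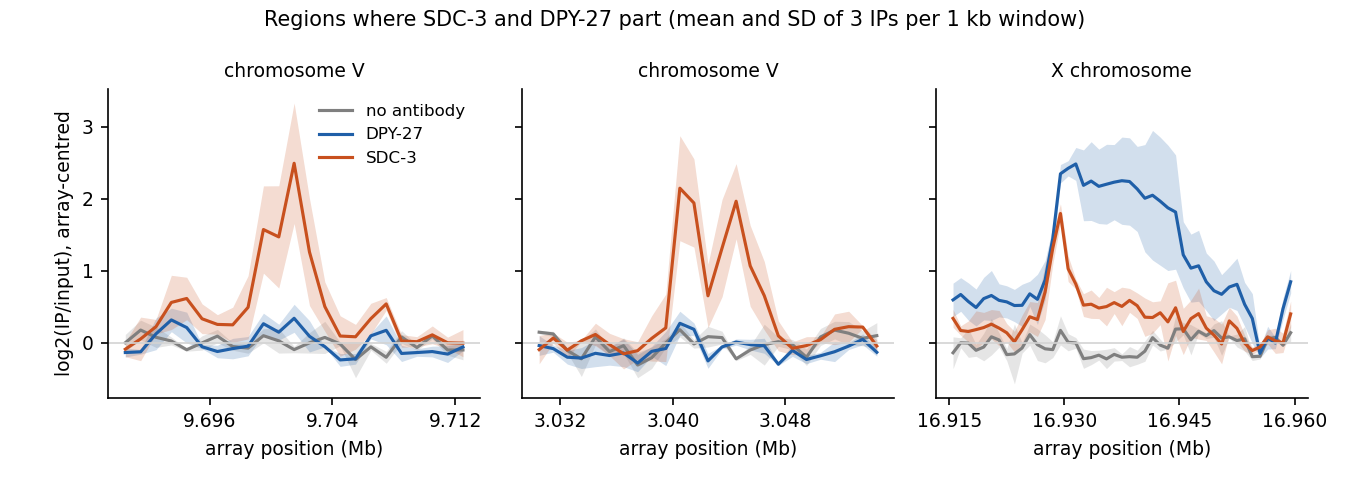
Log2(IP/input) per 1 kb window (mean, with the SD of 3 IPs shaded) around V 9,701,001, around V 3,040,001 to V 3,044,001 and around X 16,933,001. In the V regions SDC-3 rises far above the other groups, with DPY-27 at 0.34 ± 0.19 at V 9,701,001, and in the X region DPY-27 stays near 2 over several kb in which SDC-3 is near 0.5.

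Whether the proteins share sites was asked by overlap. On the X 951 of 953 SDC-3 sites overlapped a DPY-27 site, as nearly any X position would, since 2102 windows were called for both and independent lists of these sizes would share 1917. On the autosomes 26 of 148 SDC-3 sites overlapped 1 of 95 DPY-27 sites, with 27 windows called for both and 0.277 expected of independent lists. Of the 27, 25 lay on array 2, where simulations with unchanged autosomes beside the measured X called a mean of 15.8 and at most 24 for both, with more DPY-27 windows called than were observed. The simulated autosomes were not lowered by centring as the measured ones were, so this comparison does not settle how much overlap the adjustment gives. With X and autosomal windows adjusted apart 2 were left, I 5,316,001 and II 13,823,001, named after their values were seen. The 2 comparisons use the same no antibody IPs, which correlates their differences across windows. On the autosomes the correlation across windows was 0.70 on array 1 and 0.69 on array 2, with 0.50 in simulated unchanged groups that share controls, and on the X it was 0.74 with 0.50 in the simulations. Windows are not independent replicates, and the simulations leave out deviations shared by SDC-3 and DPY-27 IPs of the same number, which would raise the simulated correlation, so the excess is not read as shared binding.

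Whether X enrichment stops at the sites could be asked of few windows. After removal of windows within 2 kb of any site, 157 of 17719 X windows were left. In these the X exceeded the autosomes by 0.42 ± 0.08 for DPY-27, 0.17 ± 0.04 for SDC-3 and 0.09 ± 0.05 without antibody. The difference from no antibody was 0.34 for DPY-27 (exact permutation p 0.1) and 0.08 for SDC-3 (exact permutation p 0.2), and with equal median absolute deviations it was 0.17 and 0.04. The windows left over were selected for low values in the same IPs.

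Foci, defined after seeing the data, stood out from their local surroundings. There were 200 of DPY-27 and 158 of SDC-3 on the X, and 89 of the SDC-3 foci (56.3%) overlapped one of DPY-27. Of the X windows 132 lay in foci of both. Independent lists of called focus windows of these sizes would share 4.22. Both lists use the same no antibody IPs. Simulated unchanged groups that share them gave 0 focus windows of either protein, so they had nothing to overlap and give no chance value for the 132. At DPY-27 foci the peak windows exceeded the autosomes by 2.22 ± 0.22 for DPY-27 and 1.78 ± 0.33 for SDC-3, and at SDC-3 foci by 2.07 ± 0.24 and 2.32 ± 0.44. In the 9623 X windows at least 20 kb from any focus the excess was still 0.85 ± 0.20 for DPY-27 and 0.30 ± 0.14 for SDC-3, with 0.00047 ± 0.0067 without antibody (exact permutation p 0.1 each). SDC-3 fell from 0.49 ± 0.23 at 2 to 5 kb from DPY-27 foci to 0.30 ± 0.14 beyond 50 kb, and DPY-27 was 0.95 ± 0.24 and 0.87 ± 0.20 at those distances from SDC-3 foci. The number of foci depends on the minimum local difference, and was 1200 and 789 with none and 807 and 586 with 0.5.

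**Figure D5:**
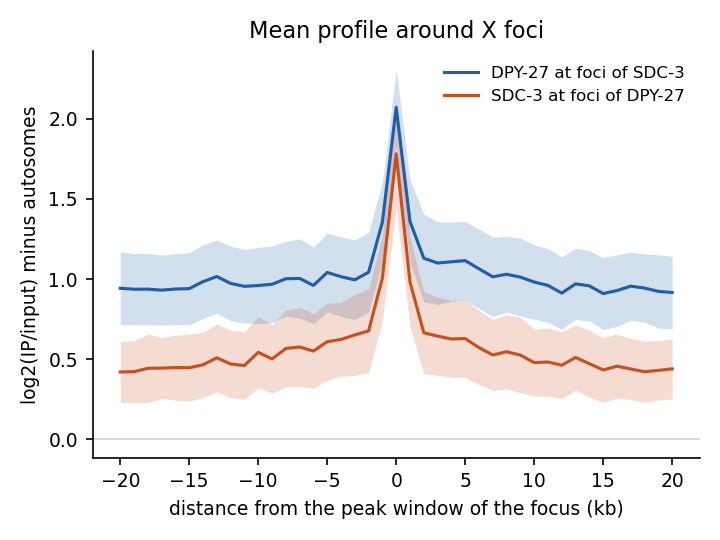
Mean profile of each protein around the X foci of the other (log2(IP/input) minus the autosomal mean, with the SD of 3 IPs shaded) against the distance in kb from the peak window. At 2 kb on the left and right of the peak DPY-27 is at 1.04 ± 0.25 and 1.13 ± 0.27, and SDC-3 is at 0.68 ± 0.26 and 0.67 ± 0.26. At 20 kb DPY-27 is at 0.94 ± 0.23 and 0.92 ± 0.23, and SDC-3 is at 0.42 ± 0.19 and 0.44 ± 0.19.

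Along the X the mean level of DPY-27, peaks included, was even, and that of SDC-3 varied more. DPY-27 was 0.91 ± 0.20, 0.90 ± 0.22 and 0.92 ± 0.21 above the autosomes in the left, middle and right parts of the X, each of equal length, and SDC-3 was 0.41 ± 0.17, 0.31 ± 0.16 and 0.46 ± 0.19 (exact permutation p 0.1 against no antibody for each). By megabase DPY-27 ranged from 0.76 ± 0.16 at 0 to 1 Mb to 0.99 ± 0.23 at 4 to 5 Mb. SDC-3 ranged from 0.27 ± 0.15 at 9 to 10 Mb to 0.67 ± 0.23 at 1 to 2 Mb, and these megabases held 3 and 21 SDC-3 foci, so the level between peaks is not told apart from the number of peaks. On the autosomes, 18 parts made in the same way differed from no antibody by -0.03 to 0.02 for DPY-27 and by -0.03 to 0.02 for SDC-3, relative to the autosomal mean of the same array.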

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

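All tests in this part were chosen only after the results were seen, except the window fits themselves and the leave-one-out fits.

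In the test between the proteins 10116 X windows were lower in SDC-3 (3407 and 5816 without DPY-27 IP 1 and 2, 6510 without SDC-3 IP 3) and 105 higher (68 without DPY-27 IP 2, 63 without SDC-3 IP 1, 224 without SDC-3 IP 3). If yield or background scaled all excess over the autosomes by 1 factor, the ratio of the excess at foci to that far from foci would stay alike. That ratio, at DPY-27 foci and on the linear scale, was 12.0 ± 4.06 for SDC-3 and 4.63 ± 0.61 for DPY-27 (SD, n = 3, exact permutation p 0.1, the smallest possible), and the lowest SDC-3 IP (9.05) was above the highest DPY-27 IP (5.25). Within each antibody, however, the ratio also rose as the excess far from foci fell. It went from 4.03 at an excess of 1.04 to 5.25 at 0.56 for DPY-27, and from 9.05 at 0.31 to 16.6 at 0.10 for SDC-3. IPs of the same antibody thus did not differ by 1 factor either, so the ratio does not settle whether yield or background is the cause. SDC-3 was called higher at 9 of the 12 named DPY-27 X sites (3 without DPY-27 IP 2 or SDC-3 IP 1, 5 without DPY-27 IP 3, 6 with autosomal centring, 4 with 2 groups in the fit, 1 with Cy5-labelled IPs alone, 12 with the replicate number as a block) and was higher at 49 of all 200 DPY-27 foci. At the SDC-3 foci it was higher at 100 of 158, and each list of foci favours the protein by which it was picked. A candidate explanation is that SDC-3 sits mainly at the strongest peaks while DPY-27 also spreads between them. A difference in yield or background, a compressed array response, which was not tested apart from the pattern itself, and antibodies that differ in access to their targets at peaks stay open.

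The 10 splits of the 6 DPY-27 and SDC-3 IPs into groups of 3 are too few for a share under 0.05. The real split called 10390 windows off the mitochondrial genome, 1 split called as many, the real one, and the highest of the others called 0.

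On the autosomes 144 windows were higher in SDC-3 than in DPY-27 and 25 lower, again by the test of the difference itself. The 144 were 61 and 77 without no antibody IP 1 and 2, 24, 60 and 93 without DPY-27 IP 1, 2 and 3 and 89 without SDC-3 IP 1. The 25 were 13, 14 and 14 without no antibody IP 1, 2 and 3, 5, 7 and 42 without DPY-27 IP 1, 2 and 3, and 15 without SDC-3 IP 1.

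For the autosomal SDC-3 sites, on array 2 the adjustment over X and autosomal windows together lets X signal admit autosomal windows. Simulations with unchanged autosomes beside the measured X gave a mean of 60.1 enriched autosomal windows and at most 74, and 74 were observed. The simulated autosomes lay at 0, while centring had lowered the measured ones (median difference -0.12 on IV and on V), so these counts are not on the same scale. How many weak autosomal calls of that array come from the adjustment is therefore not settled. The adjustment does not account for 6 windows of array 2, V 3,040,001, V 3,041,001, V 3,044,001, V 7,649,001, V 7,659,001 and V 9,701,001, which stayed called with X and autosomal windows adjusted apart, where the simulations gave a mean of 0.2 and at most 2. X fragments that hybridise to autosomal probes would bring DPY-27 too, but at the 7 autosomal SDC-3 foci (3 without no antibody IP 3, 12 without SDC-3 IP 3) DPY-27 was 0.18 ± 0.08, or 0.30 ± 0.10 above the autosomes of the same array, and SDC-3 was 1.85 ± 0.58 above them (SD, n = 3), against 2.07 ± 0.24 for DPY-27 at the X foci of SDC-3, which argues against X fragments as the whole cause. Without antibody the foci were at -0.08 ± 0.04 and each DPY-27 IP was above that (lowest 0.19), so SDC-3 binding with little DPY-27 is a hypothesis that rests on 3 IPs, absence of DPY-27 is not shown, and cross-reaction of the SDC-3 antibody with another protein stays open. In the local fit SDC-3 minus DPY-27 was not called at 3 of the 7 foci, V 3,040,001 (limma, adjusted p 0.0526), V 7,659,001 (0.0984) and II 4,701,001 (0.0592), named after their values were seen.

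The mitochondrial probes, left out of the X and autosome comparisons, were less depleted against input in DPY-27 IPs, at -1.12 ± 0.17 relative to the autosomes, than in the no antibody IPs, at -1.56 ± 0.17 (exact permutation p 0.1, the smallest possible), with -1.51 ± 0.41 for SDC-3.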

How the results depend on the processing

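All tests in this part marked as added, and all splits and simulations, were chosen only after the results were seen.

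Of 420 alternative values 249 stayed close to the main ones, 171 moved and 0 changed sign. Close meant within a fixed factor for counts and within an SD over IPs for other values. Some of the 249 could not move. They include X minus autosome differences taken within replicate numbers, and those without an IP of a group outside the comparison. The tally is therefore not a measure of robustness. A count cannot change sign, and in 13 cases the larger of the higher and lower autosomal counts changed side. DPY-27 went from 130 higher and 5047 lower to 722 and 141 with autosomal centring or as deposited, 3 and 0 with a log2 difference of at least 1 and 12 and 0 with X and autosomal windows adjusted apart. SDC-3 went from 176 and 93 to 219 and 747 with equal median absolute deviations, 81 and 93 with 2000 bp windows, 633 and 962 with the block, 1624 and 3042 against input, 103 and 233 without SDC-3 IP 2 and 217 and 434 without SDC-3 IP 3, and without DPY-27 IP 3 slightly more were lower than the 98 higher. SDC-3 against DPY-27 went from 144 and 25 to 36 and 50 with autosomal centring or as deposited. The following moved, and unless stated the cause was not tested. With 500 bp windows, DPY-27 windows enriched were 28195 on the X and 236 on the autosomes, and SDC-3 windows enriched were 3264 on the X. X windows of SDC-3 against DPY-27 were 184 higher. With 2000 bp windows, DPY-27 windows enriched were 8527 on the X and 68 on the autosomes, and SDC-3 windows enriched were 1307 on the X and 81 on the autosomes. X windows of SDC-3 against DPY-27 were 56 higher and 6184 lower, and autosomal windows of SDC-3 against DPY-27 were 12 lower. With a log2 difference of at least 1, DPY-27 windows enriched were 3003 on the X and 3 on the autosomes and those depleted on the autosomes 0, and SDC-3 windows enriched were 678 on the X and 19 on the autosomes and those depleted on the autosomes 0. X windows of SDC-3 against DPY-27 were 41 higher and 220 lower, and autosomal windows of SDC-3 against DPY-27 were 15 higher and 1 lower. Window size and thresholds change the counts by construction.

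With autosomal centring and with the values as deposited, DPY-27 windows enriched were 722 on the autosomes and those depleted on the autosomes 141, and SDC-3 windows enriched were 3557 on the X and 388 on the autosomes and those depleted on the autosomes 12. Autosomal windows of SDC-3 against DPY-27 were 36 higher and 50 lower. The fall of the depleted autosomal DPY-27 windows from 5047 to 141 follows from the centring, since centring on all probes of array 2 lowers its autosomes when the X is enriched.

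With the dye as a covariate, DPY-27 windows enriched were 358 on the autosomes, and SDC-3 windows enriched were 496 on the autosomes and those depleted on the autosomes 323. Autosomal windows of SDC-3 against DPY-27 were 314 higher and 45 lower, and DPY-27 autosomal foci numbered 4. With the replicate number as a block, DPY-27 windows enriched were 419 on the autosomes and those depleted on the autosomes 8439, and SDC-3 windows enriched were 4660 on the X and 633 on the autosomes and those depleted on the autosomes 962. X windows of SDC-3 against DPY-27 were 181 higher, and autosomal windows of SDC-3 against DPY-27 were 487 higher and 50 lower. DPY-27 autosomal foci numbered 4. With an adjusted p under 0.01, DPY-27 windows enriched were 32 on the autosomes and those depleted on the autosomes 850, and SDC-3 windows enriched were 922 on the X and 24 on the autosomes and those depleted on the autosomes 2. X windows of SDC-3 against DPY-27 were 47 higher and 3933 lower, and autosomal windows of SDC-3 against DPY-27 were 22 higher and 3 lower. With X and autosomal windows adjusted apart (added), DPY-27 windows enriched were 12 on the autosomes and those depleted on the autosomes 0, and SDC-3 windows enriched were 3317 on the X and 108 on the autosomes and those depleted on the autosomes 0. Autosomal windows of SDC-3 against DPY-27 were 4 higher and 1 lower. Without the dimmest probes, DPY-27 windows enriched were 353 on the autosomes, and SDC-3 windows enriched were 598 on the autosomes and those depleted on the autosomes 249. Autosomal windows of SDC-3 against DPY-27 were 273 higher and 39 lower. With Cy5-labelled IPs alone (added), DPY-27 windows enriched were 66 on the autosomes and those depleted on the autosomes 2469, and SDC-3 windows enriched were 572 on the X and 59 on the autosomes and those depleted on the autosomes 9. X windows of SDC-3 against DPY-27 were 27 higher and 3183 lower, and autosomal windows of SDC-3 against DPY-27 were 16 higher and 3 lower. Against input, DPY-27 windows enriched were 1299 on the autosomes and those depleted on the autosomes 14318, and SDC-3 windows enriched were 5725 on the X and 1624 on the autosomes and those depleted on the autosomes 3042. The same number of X foci with the dye or the block says nothing about stability, since balanced covariates leave the log2 differences unchanged and the minimum of 1 limits the calls.

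With equal median absolute deviations, DPY-27 windows depleted on the autosomes were 2760, and SDC-3 windows enriched were 3254 on the X and those depleted on the autosomes 747. X windows of SDC-3 against DPY-27 were 1906 lower, and autosomal windows of SDC-3 against DPY-27 were 24 higher and 2 lower. The X minus autosome difference of DPY-27 against no antibody was 0.65, and that of SDC-3 against DPY-27 was -0.28. Outside sites the difference of DPY-27 against no antibody was 0.17, and that of SDC-3 against DPY-27 was -0.13. The scale of array 2 included its X probes, so an enriched X enters it and may itself lower the scaled differences. With 2 groups in the fit, SDC-3 windows enriched were 59 on the autosomes and those depleted on the autosomes 24, and X windows of SDC-3 against DPY-27 were 63 higher and 6197 lower. Autosomal windows of SDC-3 against DPY-27 were 33 higher and 6 lower.

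With no minimum local difference (added), DPY-27 X foci numbered 1200, and DPY-27 autosomal foci numbered 16. SDC-3 X foci numbered 789, and SDC-3 autosomal foci numbered 76. With a local difference of at least 0.5 (added), DPY-27 X foci numbered 807, and DPY-27 autosomal foci numbered 16. SDC-3 X foci numbered 586, and SDC-3 autosomal foci numbered 76. With a running median over 21 windows (added), DPY-27 autosomal foci numbered 1. At SDC-3 foci (added), the SDC-3 ratio of the excess at foci to that far from foci was 19.4. A lower minimum admits more foci by construction.

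With each IP left out in turn, DPY-27 enriched autosomal windows ranged from 53 to 253 and depleted ones from 1881 to 7014. SDC-3 enriched X windows ranged from 872 to 3734, enriched autosomal ones from 24 to 217 and depleted ones from 2 to 434. X windows lower in SDC-3 than in DPY-27 ranged from 3407 to 12475 and those higher from 63 to 224. Autosomal windows higher in SDC-3 ranged from 24 to 133 and those lower from 5 to 42. Autosomal foci ranged from 1 to 11 for DPY-27 and from 3 to 12 for SDC-3.

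The replicate number was tested as a pairing by the correlation across windows of residuals of IPs from different groups. On array 1 it was -0.12 to 0.50 for 9 pairs of the same number and on array 2 -0.03 to 0.77, and 7 of 9 were over 0.1 on each. The pairs under 0.1 all held no antibody IP 1, so the numbers were not taken to pair the no antibody IPs with others, and not every IP correlated best with its own number. For SDC-3 against DPY-27 all 3 pairs were over 0.1 on each array. There the block raised the X windows higher in SDC-3 from 105 to 181, the autosomal ones from 144 to 487 and those lower from 25 to 50, and the named DPY-27 X sites called higher in SDC-3 from 9 to 12, and it changed no call of the other named windows. Within numbers the X minus autosome difference was 0.69 to 1.10 for DPY-27 against no antibody, 0.20 to 0.50 for SDC-3 and -0.60 to -0.47 for SDC-3 against DPY-27.

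The splits of the 6 IPs, 10 per contrast, are too few for a share under 0.05. DPY-27 against no antibody called 21290 windows in the real split, 1 split reached that, and the highest other called 0. SDC-3 against no antibody called 2377, 1 split reached that, and the highest other called 0.

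The named X sites of each protein kept their call against no antibody in every setting of 1 kb windows, and so did the 5 named X windows higher in DPY-27 than in SDC-3. Of the 5 named windows higher in SDC-3 than in DPY-27, all autosomal, 2 kept their call with X and autosomal windows adjusted apart and at least 4 in each other setting. Of the 8 named autosomal DPY-27 sites 2 kept their call with equal median absolute deviations, 6 with X and autosomal windows adjusted apart and 3 without no antibody IP 1 or 2 or DPY-27 IP 2. The named DPY-27 X sites called higher in SDC-3, 9 in the main result, were 6 with autosomal centring or as deposited, 4 with 2 groups in the fit, 3 at an adjusted p under 0.01, 2 with a log2 difference of at least 1 and 1 with Cy5-labelled IPs alone. They were 11 with the dye as a covariate and 12 with equal median absolute deviations, with the block, with X and autosomal windows adjusted apart and without the dimmest probes. With 1 IP left out they were 3 to 12.

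For the autosomal DPY-27 calls of array 2, simulations with unchanged autosomes gave a mean of 217 and at most 252, and 118 were observed. The simulated autosomes lay at 0, while centring had lowered the measured ones (median difference -0.17 on IV and -0.19 on V), which removes higher calls. With autosomal centring 722 were called over both arrays. The simulations therefore do not show how many of these calls come from the adjustment over X and autosomal windows together. Comparisons at gene starts and of gene lists, and their alternatives, were not run. Signal over background was checked on the 6 no antibody arrays alone, and was not analysed here for the others.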

Other observations

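All tests in this part were chosen only after the results were seen.

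DPY-27 exceeded SDC-3 over extended stretches of the X. Called windows with a log2 difference of at least 1, joined over at most 1 other window, gave 26 runs of 3 kb or longer. The longest ran for 16 kb from X 16,930,001 to X 16,946,000, with 2.09 ± 0.59 for DPY-27, 0.50 ± 0.19 for SDC-3 and -0.09 ± 0.07 without antibody (SD, n = 3). Others ran from X 3,112,001 to X 3,127,000 (SDC-3 0.38 ± 0.28), from X 5,476,001 to X 5,485,000 (DPY-27 2.08 ± 0.37, SDC-3 0.73 ± 0.29) and from X 5,819,001 to X 5,828,000 (DPY-27 1.97 ± 0.24, SDC-3 0.48 ± 0.25). If DPY-27 moved outwards from SDC-3 foci, these runs might lie beside them. Their median distance to the nearest SDC-3 focus was 63.5 kb, against 44.4 kb for random placements (two-sided permutation p 0.202), and 3 lay within 2 kb of one. As a set they were thus not seen to lie nearer to foci. The runs were chosen for low SDC-3, which keeps them off SDC-3 peaks, while random placements could fall on such peaks. The test therefore leaves the question open. The longest run began next to X 16,929,001, where the SDC-3 IPs were at 1.84, 1.90 and 1.64.

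SDC-3 foci were unevenly placed along the X. There were 21 of them between 1 and 2 Mb and 2 between 3 and 4 Mb, and DPY-27 foci numbered 15 and 3 in the same megabases. The gaps between SDC-3 foci had a coefficient of variation of 1.22, against 0.988 for random placements (two-sided permutation p 0.0136, adjusted p 0.0272 over 2 tests), and for DPY-27 foci it was 1.07 (permutation p 0.243, adjusted p 0.243). Random placement of SDC-3 foci is thus unlikely at the value of 1.22, but clusters may be single broad sites that the focus step divided, which was not tested. The difference between the proteins in this value was not tested.

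One region was high in the no antibody IPs. At X 5,908,001 the no antibody IPs reached 3.44 ± 0.75, DPY-27 2.21 ± 0.64 and SDC-3 2.75 ± 0.78 (SD, n = 3), and at X 5,911,001 the values were 3.27 ± 0.44, 2.22 ± 0.59 and 2.56 ± 0.66. At X 5,910,001 they were 2.02 ± 0.84, 0.73 ± 0.58 and 1.23 ± 1.65, so the IPs of SDC-3 differed widely there. These were the 3 windows outside the mitochondrial genome in which each no antibody IP was at least 1.

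DPY-27 IP 3 on array 1 was the noisiest array. Its neighbouring autosomal probes correlated with r of 0.0738 across probes, against 0.339 to 0.568 on the other 17 arrays, and its probe values had an SD of 0.53. Without this IP the autosomal DPY-27 foci rose from 2, at II 13,599,001 and IV 3,367,001, to 11. The 2 were also 1 without no antibody IP 2 or 3, DPY-27 IP 2 or SDC-3 IP 1 or 3, and 4 without SDC-3 IP 2.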
